A study of Mus musculus with 16 samples.

How the data were processed

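Muscle stem cells from skeletal muscle of C57BL/6 mice were assayed for H3K4me3 and H3K27me3 in a quiescent (QSC) and an activated (ASC) state. Each of the 4 combinations had 2 immunoprecipitated replicates, each with an input sample, 16 samples in all; groups were taken from the sample titles. Per the labels' protocols, chromatin from sonicated nuclei was immunoprecipitated, antibody-bound DNA was tagmented with a TruePrep kit (ChIPmentation) and libraries were sequenced on a NextSeq 500 as 2 reads of 75 bp. Per the submitters' processing notes, the tools were bcl2fastq 2.19, Trimmomatic 0.36, Bowtie2 2.3.2, Picard 2.9.2, SAMtools 1.3, MACS2 2.1.1 and bedtools 2.26.0 and the build was mm10; their settings are not given in the sources used here. How the cells were isolated or activated is also not given there, nor whether replicates came from separate animals.

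The data used were 8 peak lists deposited by the authors, a narrow and a broad list for each state and mark. The labels name the same lists for both replicates of a group, so each list is treated as a pooled result of its group. For each peak the authors deposited a fold enrichment over background (a linear ratio) and the -log10 of a p-value and of a q-value. The fold per peak is the authors' own value and was used to describe, rank or filter peaks within a list. Numbers in the peak names run beyond the number of peaks, so the deposited lists hold part of the peaks first called: 63.2% and 62.0% of the H3K4me3 narrow peaks in QSC and ASC, and 71.3% and 49.9% of the H3K27me3 broad peaks. The median -log10 q was 29.9 and 79.6 for H3K4me3 narrow peaks and 0.42 and 0.38 for H3K27me3 broad peaks, per the deposited files. Read depth per sample is unknown from these files, so no interval that needs counts is given. The signal tracks were not analysed here.

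Gene records came from the RefSeq gene table for GRCm38.p6, which shares its coordinates with mm10. It gives the ends of each gene record without strand or transcript starts, and no genome sequence was used here. The planned window was one of 1 kb either side of the gene start. Without strand, the window was placed at both ends of the record, for 21887 protein-coding genes on the autosomes, X and Y. A start that lies inside a longer record is missed by these windows, and a peak at a shared end is counted for each gene there. A gene was called for H3K4me3 when a narrow peak overlapped a window by at least 1 bp, and for H3K27me3 when broad peaks covered at least 500 bp of a window. It was bivalent when both calls fell at the same end. The number of gene ends with both marks was set beside the product of the separate counts divided by all ends. H3K4me3 domains were narrow peaks merged over gaps of up to 1 kb, and the longest domain touching a window gave the length for that gene. H3K27me3 domains were broad peaks merged over gaps of up to 3 kb. Peaks were shared when they overlapped by at least 1 bp.

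A total of 21 gene lists were fixed before the data were examined: quiescence and satellite cell identity, myogenic regulators, sarcomere, cell cycle, cyclin-dependent kinase inhibitors, Notch, Wnt, immediate early and stress response, extracellular matrix, Hox, neural regulators, other mesoderm and endoderm regulators, Polycomb and Trithorax enzymes, ribosome biogenesis, glycolysis and energy metabolism, markers of 5 other cell types and ubiquitously expressed reference genes. All 610 symbols, counted per list, matched a current symbol or a unique synonym, and the quiescence list held 36 symbols for 35 genes because Odz4 and Tenm4 name the same gene. Each count or median was placed among 10000 random lists of the same size, as a description of these lists of peaks with no p-value. Matching on promoter GC content was planned and was not run without a genome sequence. The genes named follow a rule of the same plan: list members, first those whose call differs between states; the 10 genes with the highest fold (H3K4me3) or most covered bases (H3K27me3) among those called in a single state with no peak of either list of the other state within 5 kb; the genes of the 10 longest domains of each mark and state; and the 10 genes with most H3K27me3 within 5 kb among those that kept H3K4me3 and had H3K27me3 in a single state. Provisional symbols were left out. List members given as examples beyond this rule were chosen after their values were seen.

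Alternatives were a -log10 q of at least 5, a fold of at least 3, equal numbers of peaks, equal covered bases, windows of 500 bp and 2.5 kb, larger overlaps (200 bp for H3K4me3 and 1000 bp for H3K27me3), the other list of each mark, all 49943 annotated genes, and other merging gaps and overlaps. Chosen after seeing the data were narrow lists for both marks, a q of at most 0.05, a single end per gene, H3K4me3 peaks set to 1 kb, and random lists matched on gene length, domain length or fold. The setting of a single end per gene kept only genes with H3K4me3, in either state, at a single end. Both marks were then counted at that end alone. The calling code was tested on simulated peaks planted at isolated genes for the comparison of QSC with ASC: all 1000 shared, 200 QSC-only and 200 ASC-only genes were recovered for each mark, and covered bases in 500 windows equalled those from bedtools 2.31.1. Of 1000 unchanged random lists of 45 genes, 24 passed the upper limit used for lists, as did 100 of 100 lists with 6 planted genes. The planted lists all held the same count, so their outcome was fixed in advance and does not measure sensitivity. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.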

Results

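Skeletal muscle stem cells (satellite cells) of C57BL/6 mice were profiled for H3K4me3, a histone mark found at active or poised promoters, and H3K27me3, the repressive mark deposited by Polycomb complexes. The cells were quiescent (QSC) or activated (ASC). The 16 libraries comprised 8 immunoprecipitated samples, with 2 replicates of each mark in each state, and 8 matched input samples. The values used here were 8 peak lists, a narrow and a broad list for each mark and state. Each list was shared by the replicates of its group, so no difference between QSC and ASC has a replicate check, and read depth per library is unknown from the files used here. Coordinates are in mm10. Genes were called at windows of 1 kb either side of each end of the gene record, because the annotation used gave no strand; the word promoter below means a gene with a call at either end.

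Genes of the cell cycle had more H3K4me3 narrow-peak calls in activated cells, whereas the genes that define satellite cells carried the mark in both states. Of 45 cell cycle and DNA replication genes, 39 had an H3K4me3 peak in QSC and 44 in ASC. The 5 called in ASC only were Tk1 (thymidine kinase), Cdc25c (a phosphatase that activates the mitotic kinase), Bub1 and Cdc20 (spindle checkpoint) and Ccnb2 (cyclin B2), and none was called in QSC only. The ASC peaks at Cdc25c, Bub1, Cdc20 and Ccnb2 had fold enrichments over background of 15.2, 21.9, 23.8 and 18.6, and the peak at Tk1 (5228 bp) also covered an end of Afmid. A random list of this size held fewer ASC-only genes in 97.85% of 10000 draws. All 5 had a peak of the QSC broad list at the window, and with the broad lists the ASC-only count was 0. The QSC broad list is far longer than that of ASC, with 184538 peaks against 29297. Of 35 genes of quiescence and satellite cell identity, 33 were marked in QSC and 33 in ASC, with no gene called in a single state. Pax7, the transcription factor that specifies satellite cells, had fold enrichments of 26.4 in the QSC list and 47.0 in the ASC list; these folds were computed by the authors within each list and give no change between lists.

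Neural lineage regulators were another group with added H3K4me3 calls in ASC. Among 40 neural lineage regulators, 14 were marked in QSC and 20 in ASC. Those called in ASC only were Pou3f3, Gbx2, Tlx3, Dlx2, Nkx2-2, Sox2, Emx1 and Nkx6-2, and those in QSC only were Barhl1 and Sox3. Random lists held fewer ASC-only genes than these 8 in 100% of draws. Their peaks were weak, from a fold of 3.43 at Nkx2-2 to 9.21 at Gbx2, and with equal numbers of peaks in the lists the ASC-only count fell to 3. All 8 had a peak of the QSC broad list at the window, and the count was 1 with the broad lists and 0 with equal covered bases. Among 50 other mesoderm and endoderm regulators, 22 were marked in QSC and 26 in ASC. Meox2, Ebf2, Runx1, Shox2 and Mesp1 were called in ASC only, more than in 96.8% of random lists, and Tbx1 in QSC only. All 5 had a peak of the QSC broad list at the window, the peak at Shox2 also covered an end of Rsrc1, and the count was 3 with equal numbers of peaks and 1 with equal covered bases. Runx1, a transcription factor expressed in regenerating muscle, stood apart with a fold of 34.5 and a peak of 6098 bp (chromosome 16, 92820911 to 92827008), while Meox2 had 3.97 and Ebf2 3.61.

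Myogenic regulators were marked much alike in the states, with 18 of 27 in QSC and 19 in ASC. The addition was Eya2, a transcriptional cofactor. Myf5, which commits cells to the muscle lineage, was called in both states with folds of 19.1 and 35.6 in the QSC and ASC lists, and Myod1 with 27.1 and 30.8. Myog, which drives terminal differentiation, had no peak of either mark at its ends in either state. Of 39 sarcomere and differentiated muscle genes, 9 were marked in QSC and 12 in ASC, fewer than most random lists. The additions were Ttn, Acta1 and Tnnc1, and the peak at Tnnc1 also covered an end of the neighbouring gene Nisch. Of 40 extracellular matrix genes, 29 were marked in QSC and 32 in ASC. Col1a1, Col14a1, Tnc and Timp1 were called in ASC only and Eln in QSC only. The ASC-only count of matrix genes was 2 with equal numbers of peaks, and lower still with equal covered bases and with the broad lists. Among 40 Wnt pathway genes the counts were 25 and 27, with Wnt10a, Lgr5 and Fzd6 called in ASC only and Wnt7a, a ligand that acts on satellite cells, in QSC only.

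Lists with no gained or lost H3K4me3 were those of Notch signalling (21 of 25 genes in each state), immediate early and stress response (31 of 32), Polycomb and Trithorax enzymes (26 of 28), ribosome biogenesis and translation (29 of 30), glycolysis and energy metabolism (26 of 31), cyclin-dependent kinase inhibitors (6 of 7) and ubiquitously expressed reference genes (19 of 20). Among markers of other cell types of muscle, endothelial and immune markers carried H3K4me3 less often than most random lists. Endothelial markers went from 4 to 5 of 17 with Cldn5, immune markers from 2 to 3 of 20 with Cd68, and fibro-adipogenic and fibroblast markers from 8 to 10 of 18 with Col1a1 and Cd248. Schwann and glial markers stayed at 5 of 13. Pericyte and smooth muscle markers went the other way, from 9 to 7 of 13, with Myh11 and Tagln called in QSC only, more than in 99.56% of random lists. Both had a peak of the ASC broad list at the window.

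Across 21887 protein-coding genes, 11595 (53.0%) carried H3K4me3 in QSC and 12200 (55.7%) in ASC. The mark was shared by 11425 genes, with 170 in QSC only and 775 in ASC only. Genes with a peak in a single state and no peak of either list of the other state within 5 kb were rare. High folds among the 28 such genes of ASC belonged to Rin1, a Ras effector (28.5, peak of 3870 bp at chromosome 19, 5050294 to 5054163), Kcnn4, a calcium-activated potassium channel (21.9, 3224 bp), Nrn1 (peak of 5469 bp), Tmem74b (7.88) and Mab21l2 (7.22), with lower values at Lpcat2, Fam131c, Slc6a17 and the muscle Kelch protein gene Klhl40. In QSC 10 genes qualified, with lower folds, among them Atp2b3, a plasma membrane calcium pump (5.81), Tubb4a (4.36), C1ra (3.87), Mrgprf (3.51), Dusp26, Cox4i2, Col6a6, Sptssb and Cox6b2 (2.47). The excess of ASC-only over QSC-only genes was 605, but reversed to -3406 when the lists were shortened to equal covered bases and to -1920 with the broad lists. The broad lists are unequal, with 184538 peaks in QSC and 29297 in ASC.

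**Figure D1:**
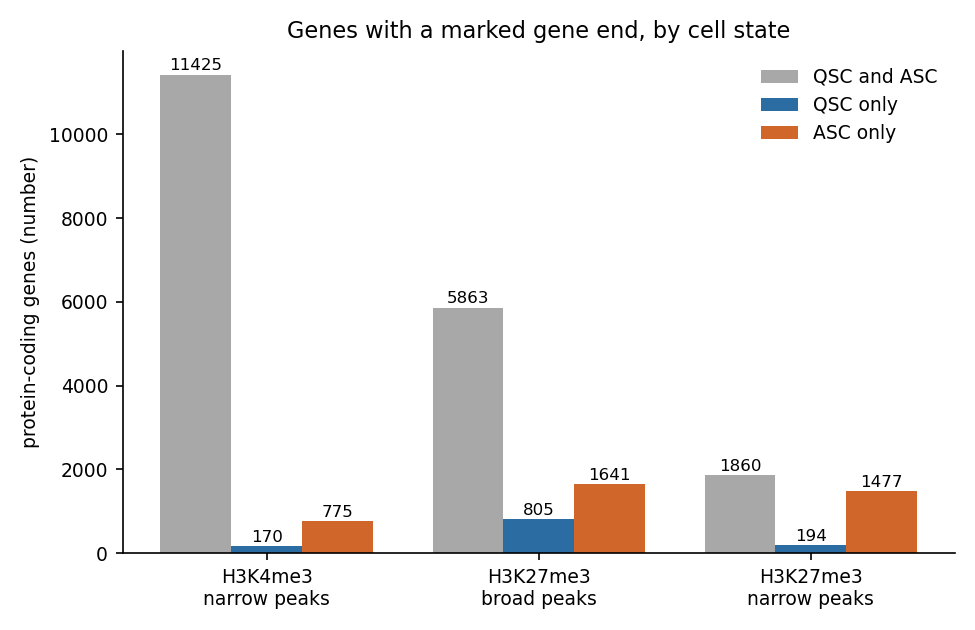
Protein-coding genes (vertical axis, number) with each mark at a gene end, as bars for genes called in both states (grey), QSC only (blue) and ASC only (orange). H3K4me3 was called in ASC only at 775 genes and in QSC only at 170, and H3K27me3 at 1641 and 805 genes by broad peaks and at 1477 and 194 genes by narrow peaks.

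H3K4me3 domains were longer in ASC at most genes, and the difference was uneven among gene groups. At the 39 cell cycle genes marked in both states the median log2 ratio of domain length, ASC over QSC, was 1.25, against 0.55 for all 11425 genes marked in both states. Rrm2, a subunit of ribonucleotide reductase, had a domain of 935 bp in QSC and 4369 bp in ASC, Top2a 412 and 2570 bp, Mcm3 of the replicative helicase 638 and 2040 bp, and Cdk1 1299 and 3463 bp. In contrast, the 33 genes of quiescence and satellite cell identity had a median of 0.02, with 14 of them shorter in ASC. The domain at Pax7 measured 17118 bp in QSC and 16898 bp in ASC. Domains were shorter in ASC at Chrdl2 (5413 and 1701 bp), Gpx3, a secreted glutathione peroxidase (8271 and 4104 bp), the Notch target Heyl (7756 and 4316 bp) and Cdh15, which encodes M-cadherin (5537 and 2659 bp).

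The cell cycle median was above that of 100% of random lists, and the quiescence median below that of every random list drawn. Other lists with high medians were ubiquitously expressed reference genes (1.09, above 100% of random lists), glycolysis and energy metabolism (0.75, above 98.5%) and ribosome biogenesis and translation (0.69, above 94.7%). Hox genes had a median of 0.77, but neighbouring Hox genes share merged domains, so their values are not separate and no place among random lists is given. Low medians were found for immediate early and stress response genes (0.19, above 0.01% of random lists), extracellular matrix (0.26, 0.14%), Wnt pathway (0.25, 0.29%), Notch pathway (0.31, 1.54%) and myogenic regulators (0.31, 1.80%). Among lists matched on mean domain length the Notch and myogenic medians lay above 3.21% and 12.4%, and among lists matched on fold rank above 0.66% and 0.7%. Within the myogenic list the domain at Myf5 went from 6277 to 11821 bp, where in ASC it was merged with that of the neighbouring Myf6, and that at Id2, an inhibitor of basic helix-loop-helix factors, from 3286 to 9192 bp, while Myod1 had 5094 and 4951 bp. Intermediate medians were those of Polycomb and Trithorax enzymes (0.41), sarcomere genes (0.34), neural regulators (0.59), other mesoderm and endoderm regulators (0.41) and cyclin-dependent kinase inhibitors (0.54). Among the inhibitors, the domain at Cdkn1b (p27) measured 4849 bp in QSC and 14786 bp in ASC. Markers of endothelial, Schwann and glial, fibroblast and pericyte cells had medians of 0.43, 0.50, 0.37 and 0.32 over 4, 5, 8 and 7 genes, and only 2 immune markers were marked in both states.

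**Figure D2:**
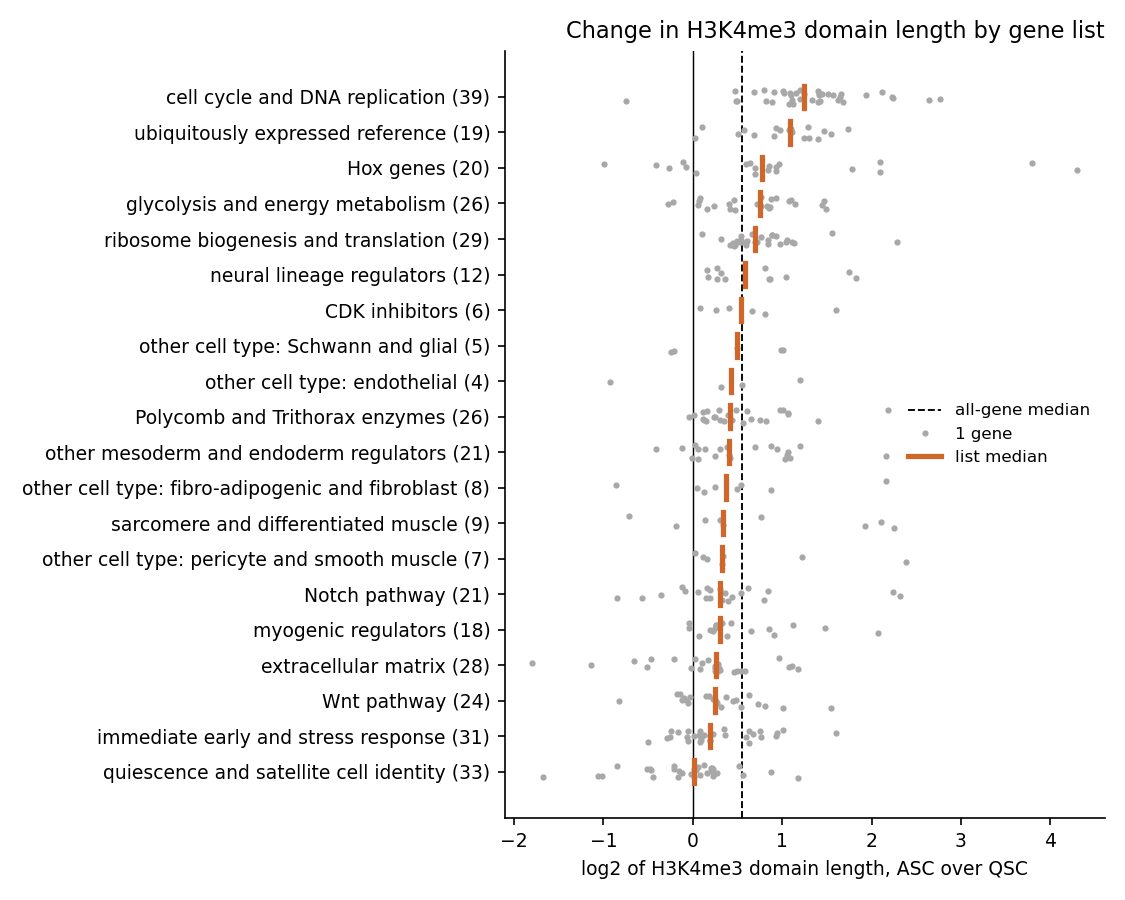
Log2 ratio of H3K4me3 domain length, ASC over QSC (horizontal axis), for the genes of each list that were marked in both states (number in brackets); grey points are genes, orange bars list medians and the dashed line the median of all genes. List medians run from 0.02 for quiescence and satellite cell identity to 1.25 for cell cycle and DNA replication, around 0.55 for all genes.

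The longest H3K4me3 domains included those at Hox genes and Pax7. In QSC the longest covered Hoxc10 and Hoxc11 (23875 bp), followed by Hoxa9 and Hoxa10 (20338 bp), Pax7, Nfib (16579 bp), Kdm6b with Dnah2 (14580 bp), Hoxc9, Sdc4, which encodes the satellite cell proteoglycan syndecan-4 (11900 bp), Htra3 (11373 bp), Bcl6 and Tshz3. In ASC a single domain of 45438 bp covered Hoxc9, Hoxc10 and Hoxc11, and another of 33096 bp reached the ends of Hoxa3, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and Hoxa11. Other long ASC domains lay at Nfib, Pax7, Zeb2 (16119 bp in ASC against 3555 bp in QSC), the stretch with Eno3 and Pfn1 (15834 against 4782 bp), Bahcc1, Cdkn1b and Frmd8 (14303 against 1606 bp). The median domain was 1819 bp in QSC and 2674 bp in ASC, and 90.7% of shared genes had the longer domain in ASC. Lengths depend on where peak calling ends a peak, and the ASC list had higher enrichments (median fold 16.3 against 10.4 per peak).

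H3K27me3 was called at more collagen and other matrix genes in activated than in quiescent cells. Of 40 extracellular matrix genes, 15 carried H3K27me3 in QSC and 23 in ASC. The 10 called in ASC only were Timp3, Col1a1, Col1a2, Col4a1, Col4a2, Col5a1, Col12a1, Col15a1, Eln and Mmp3, more than in 99.96% of random lists, but the count was 1 with a fold of at least 3 and 2 with a -log10 q of at least 5. Lama4 and Tnc were called in QSC only, and Tnc, a matrix glycoprotein of regenerating muscle, had H3K4me3 but no H3K27me3 call in ASC. Col15a1 had a broad peak of 78661 bp in ASC (chromosome 4, 47167543 to 47246203) and no H3K27me3 peak of either list within 5 kb of its ends in QSC. The shared ends of Col4a1 and Col4a2, the basement membrane collagen pair, lay in an ASC peak of 29710 bp with no QSC peak within 5 kb. With narrow peaks the matrix counts were 3 in QSC and 9 in ASC, and 6 genes were called in ASC only, more than in 94.9% of random lists; these were Col4a1, Col4a2, Col12a1 and Col15a1 of the genes above, with Col6a2 and Fbn2.

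Genes of differentiated muscle, Wnt signalling and the quiescent state also had H3K27me3 calls in a single state. By broad peaks their ASC-only counts were not unusual among random lists. The counts lay above 92.9% of lists for sarcomere, 82.7% for Wnt, 73.8% for quiescence and 85.9% for myogenic genes. Of 39 sarcomere genes, 13 were called in QSC and 18 in ASC. The ASC-only genes included the myosin heavy chains Myh2, Myh4, Myh7 and Myh8, myoglobin (Mb) and Tnnc2; at Myh2 the ASC peak measured 19961 bp. The ASC-only count was 1 with a -log10 q of at least 5. It was 0 with a single end per gene, a setting that counts H3K27me3 only at an end with H3K4me3. Acta1 was the only sarcomere gene with both marks at the same end in ASC, so the ASC-only genes could not count there. Narrow peaks called 4 sarcomere genes in each state, with Myl2 and Ckm in QSC only and Myh3 and Myh2 in ASC only. Among 40 Wnt pathway genes, 30 were called in QSC and 34 in ASC by broad peaks, and 18 and 28 by narrow peaks. The 10 Wnt genes with narrow peaks in ASC only included Wnt2, Wnt4, Wnt5a and Wnt6, more than in 99.98% of random lists. Of these 10, Wnt2, Wnt2b, Wnt5a, Wnt6, Fzd6, Rspo3 and Dkk2 already had H3K27me3 in QSC by broad peaks. Wnt4 and Fzd9 alone were also called in ASC only by broad peaks. The random lists were not matched on H3K27me3 in QSC. Of the quiescence genes 5 were called in QSC and 7 in ASC. Calcr, the calcitonin receptor that keeps satellite cells quiescent, Chrdl2, Bmp4 and Col5a1 were called in ASC only, and Six4 and Sdc3 in QSC only. At Chrdl2, 6781 bp within 5 kb of a gene end were covered in ASC and 0 bp in QSC. Narrow peaks held this call at Chrdl2 and Bmp4. Myogenic regulators had 5 calls in QSC and 9 in ASC, with Igf1, Dach1, Boc and Mymx called in ASC only, though at Dach1 a QSC broad peak of the same fold (2.42) lay within 5 kb. Pax7 and Myf5 had no H3K27me3 within 5 kb in either state.

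A minority of lists had fewer H3K27me3 calls in ASC. Immediate early genes went from 8 to 5 of 32, with Ier5, Fosl1 and Dusp2 called in QSC only, and cell cycle genes from 4 to 2 of 45, with Rrm2 and Mki67 called in QSC only. Neither change was present in the narrow lists, which held 4 immediate early genes and 1 cell cycle gene in each state. Neural regulators were called at all 40 genes in both states, other mesoderm and endoderm regulators at 43 of 50 in each, with Runx2 called in QSC only and Lbx1 in ASC only, and the reference genes at 0 of 20 in each. The Notch list went from 6 to 7 of 25 with Nrarp, Polycomb and Trithorax enzymes from 5 to 7 of 28 with Cbx7 and Ring1, and glycolysis and energy metabolism from 7 to 8 of 31. Ribosome genes had 2 of 30 in each state, with Npm1 called in QSC only and Rpl5 in ASC only, and cyclin-dependent kinase inhibitors 3 of 7, with Cdkn2b called in QSC only and Cdkn1a in ASC only. Markers of immune cells went from 13 to 17 of 20, with 4 called in ASC only. That ASC-only count was 0 with a fold of at least 3 or a -log10 q of at least 5, and 2 with narrow peaks. Schwann and glial markers went from 8 to 10 of 13, fibroblast markers from 6 to 8 of 18, and pericyte and smooth muscle markers from 5 to 7 of 13. In this last list Myh11, Pdgfrb, Mcam and Cspg4 were called in ASC only, more than in 98.73% of random lists, and Higd1b and Abcc9 in QSC only; with narrow peaks 2 genes were called in ASC only. Endothelial markers had 13 of 17 in each, with Pecam1 called in QSC only and Egfl7 in ASC only.

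**Figure D3:**
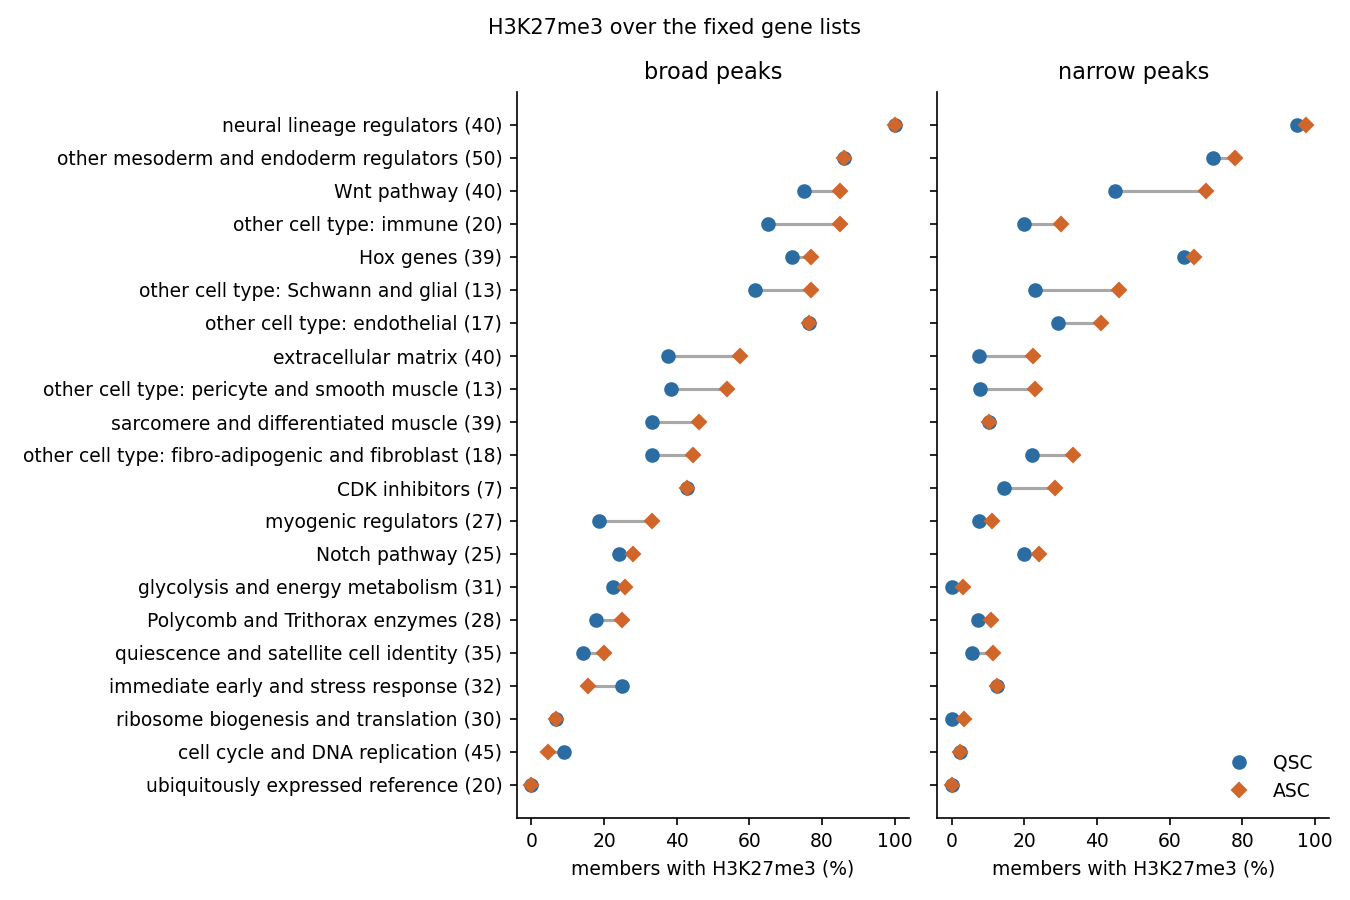
Share of the members of each fixed gene list (number of measured genes in brackets) with H3K27me3 at a gene end in QSC (blue circles) and ASC (orange diamonds), from broad peaks (left) and narrow peaks (right). Extracellular matrix genes went from 15 to 23 of 40 with broad peaks and from 3 to 9 with narrow peaks, and Wnt pathway genes from 30 to 34 and from 18 to 28.

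H3K27me3 was called at 6668 genes (30.5%) in QSC and 7504 (34.3%) in ASC, with 5863 shared, 805 in QSC only and 1641 in ASC only. The most covered ASC-only genes with no QSC peak within 5 kb, out of 355, were Col15a1, Crispld2, Myh2, Tmem51, Col4a1 and Col4a2, the endothelial gene Egfl7, Gc, Vmn1r49, Vmn1r46 and Oosp2; narrow ASC peaks were also present at the first 6 of these. Their QSC counterparts, out of 157, were Mep1b, Akr1c14, Camkk2, Uox, Fosl1, Otub2, Runx2, Rpl32l, Ngp and Ptpn22, of which Runx2 alone also had a narrow QSC peak at its ends. The broad lists were permissive: 96.2% of QSC peaks and 91.5% of ASC peaks had a q value above 0.05 in the authors' files. With narrow lists the counts were 194 in QSC only and 1477 in ASC only, and with a single end per gene 112 and 775. The single-end counts cover only genes with H3K4me3 at a single end, and H3K27me3 at that end, so they describe a smaller set of genes. With broad peaks of -log10 q of at least 5 the counts were 3 and 922, but this limit left 71 peaks in QSC and 874 in ASC. The list of QSC was then nearly empty.

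Promoters with both marks at the same end, called bivalent here, were more frequent in activated cells. The count was 1168 genes in QSC and 2251 in ASC, and 366 and 1131 with narrow H3K27me3 peaks. In these classes, H3K4me3 alone means that the marks shared no end, so such a gene can carry H3K27me3 at its other end. Of the genes with H3K4me3 alone in QSC, 802 were bivalent in ASC, and of those with H3K27me3 alone, 429 were. A further 987 genes were bivalent in both states, 113 became H3K4me3 alone and 67 H3K27me3 alone. The 802 and 113 are changes of class and not always gain or loss of H3K27me3 at the gene. Genes that kept H3K4me3 and had H3K27me3 in ASC only, with none within 5 kb in QSC, were led by Col15a1, Tmem51, Col4a1 and Col4a2, Htra3, Card10, Cyb561, Camk2n1, Kazn, Hmcn2, and Hsf4 with Fbxl8. At Htra3, a secreted serine protease gene, the H3K4me3 domain measured 11373 bp in QSC and 2285 bp in ASC, with 9678 bp of H3K27me3 within 5 kb in ASC. The reverse pattern was led by Camkk2, Fosl1, Kcnq5, Lgals3, Gmip, Ipo8, Rrm2, Mafg, Tpd52l1 and Flrt2, and at these 10 genes no narrow H3K27me3 peak was present in QSC.

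Bivalent genes were frequent among developmental regulators and in some other lists. Among neural regulators 13 genes were bivalent in QSC and 20 in ASC, among other mesoderm and endoderm regulators 16 and 20, among Wnt pathway genes 14 and 19 and among extracellular matrix genes 6 and 16. Each of these counts was above that of at least 98.2% of random lists, but the matrix count in QSC was above 91.6% of lists matched on gene length, and with narrow H3K27me3 peaks it was 0 in QSC and 5 in ASC. Immediate early and stress response genes had 5 in QSC (Ier5, Egr2, Egr3, Fosl1 and Dusp2), above 99.4% of lists matched on gene length, and 3 in ASC. With narrow H3K27me3 peaks this list had 1 in QSC (Egr2), above 63.5% of lists matched on gene length, and 2 in ASC. Neither the high place nor the direction was thus kept. Hox genes had 8 and 11, with no place among random lists given because single peaks span several of them. Pax3, the paralogue of Pax7, was bivalent in both states, with folds for H3K4me3 of 8.71 and 8.13 in the QSC and ASC lists and H3K27me3 broad peaks of 3.16 and 3.82. Cdkn2a, the senescence locus, and Cdkn1c were also bivalent in both states by broad peaks, but with narrow H3K27me3 peaks only Cdkn1c was, in ASC alone. Over all gene ends the marks coincided less often than independent placement gives, at 1198 ends against 2780.8 in QSC and 2355 against 3441.2 in ASC. A peak list cannot tell a nucleosome with both marks from a mixture of cells. The direction of the difference reversed, to 1168 in QSC and 462 in ASC, when the lists were shortened to equal covered bases.

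The Hox clusters divided by cluster more than by state. All 10 Hoxb genes and all 9 Hoxd genes carried H3K27me3 in both states, and broad peaks covered 100% of each cluster. Hoxb had no H3K4me3 peak, and Hoxd had H3K4me3 at Hoxd9, Hoxd8 and Hoxd3 alone. In the Hoxa cluster (chromosome 6, 52155367 to 52260880) H3K4me3 peaks covered 35.4% of the span in QSC and 48.0% in ASC, and in the Hoxc cluster (chromosome 15, 102921131 to 103036856) 46.8% and 55.6%. Hoxa5, Hoxa6 and Hoxa9 and the Hoxc genes Hoxc4, Hoxc6, Hoxc8, Hoxc9, Hoxc10 and Hoxc11 had no H3K27me3 call in either state. Hoxc12 and Hoxc13 had H3K4me3 calls in ASC only, inside H3K27me3, with folds of 6.14 and 6.68. In total 20 of 39 Hox genes carried H3K4me3 in QSC and 22 in ASC, and H3K27me3 was called at 28 and 30.

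**Figure D4:**
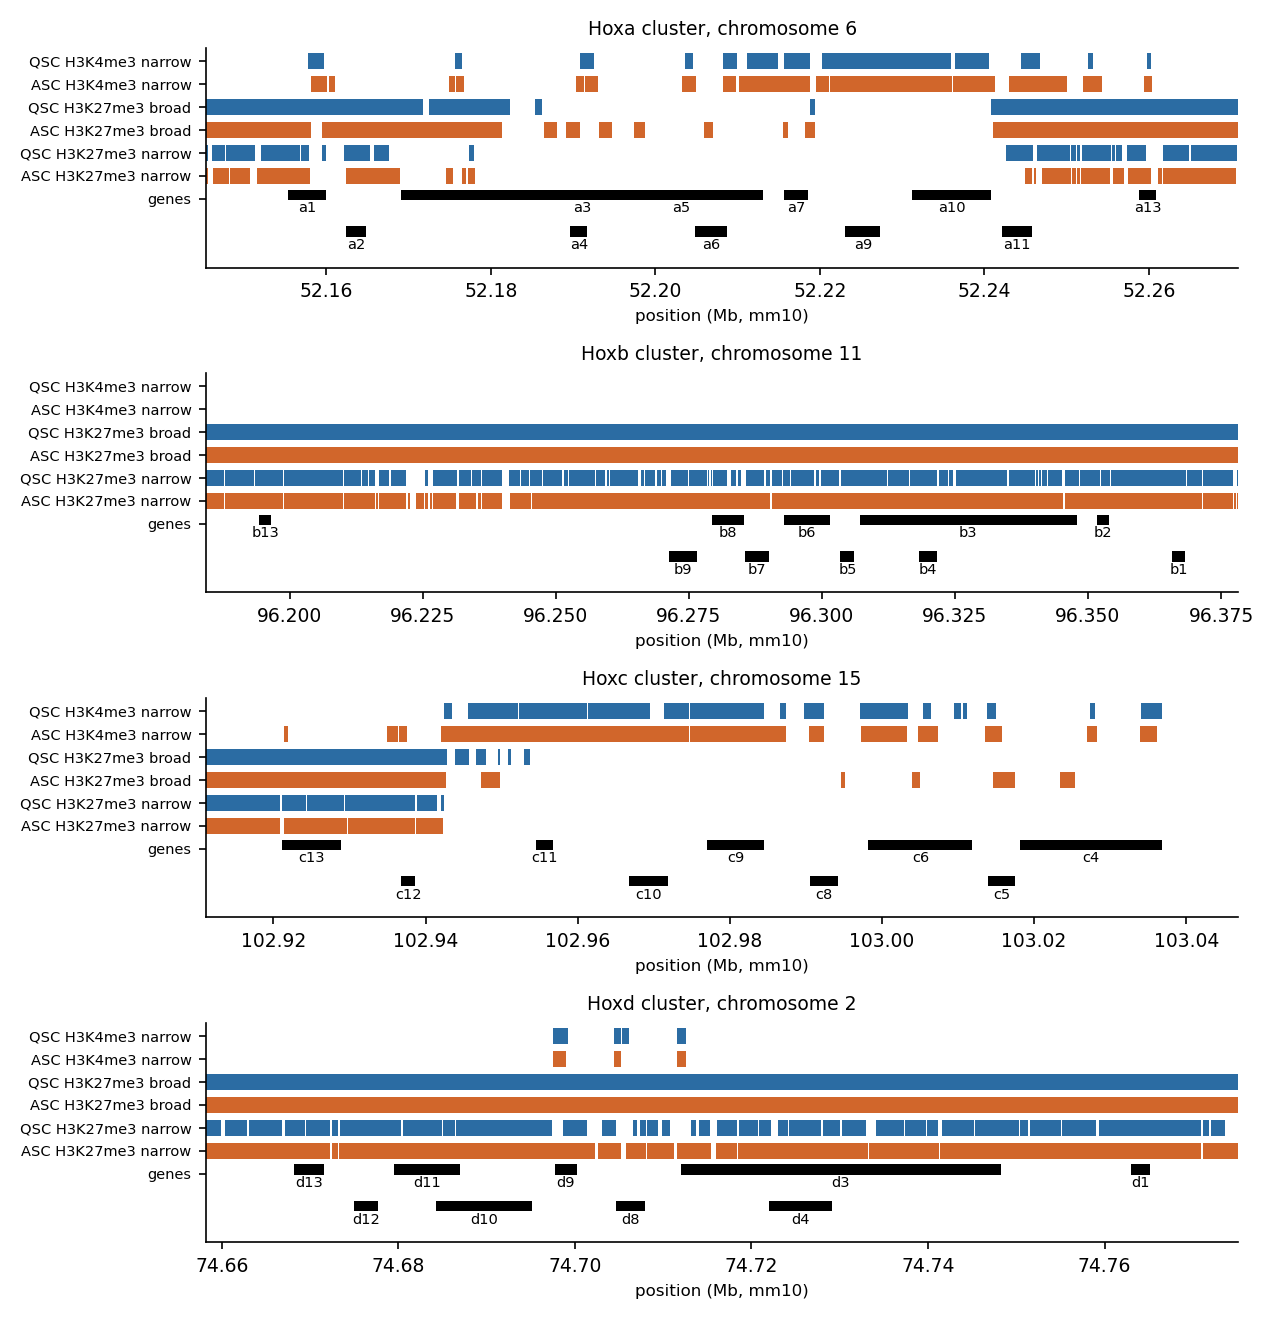
Peaks of each list (one track per list; QSC blue, ASC orange) along the Hoxa, Hoxb, Hoxc and Hoxd clusters, with gene records in black and positions in Mb of mm10 on the horizontal axes. H3K27me3 covers 100% of the Hoxb and Hoxd spans by broad peaks in both states, while H3K4me3 covers 35.4% of the Hoxa span in QSC and 48.0% in ASC.

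Long H3K27me3 domains lay at Hmga2, at the Hoxb cluster and at Otx2. Some of the longest in each state held no protein-coding gene once genes with provisional symbols were left out. A gene with any overlap was counted as held by a domain. Hmga2, a chromatin protein of growing cells, lay in the longest QSC domain, 540.8 kb on chromosome 10 (120235235 to 120775984), of which broad peaks covered 94.7% in QSC and 55.8% in ASC, and narrow peaks 33.8% and 22.6%. Its H3K4me3 domain measured 2275 bp in QSC and 6502 bp in ASC. Other long QSC domains held Cbln1 with Zfp423 (522.7 kb), Cadm1, Peli2, Ncoa3 with Sulf2, Dact2 with Smoc2, and Ldlrad3 with Trim44, where broad coverage was 96.2% in QSC and 72.3% in ASC. The longest ASC domain, 685.6 kb on chromosome 11, held the Hoxb cluster and was covered to 98.5% in each state. It was followed by domains at Ntm (526.3 kb), Foxb1 (484.1 kb), Cbln1 with Zfp423, Sulf2, Camk2n1 with Pla2g2 genes, the forebrain regulator Otx2 (399.6 kb; coverage of 74.2% in QSC and 96.5% in ASC) and Sox1. Domains over 50 kb numbered 1810 in QSC and 2080 in ASC, and 3887 and 3869 when gaps of up to 10 kb were merged.

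H3K4me3 peaks were largely shared between the states and H3K27me3 peaks less so. Of H3K4me3 narrow peaks, 94.9% of the 14354 in QSC and 86.3% of the 15869 in ASC overlapped a peak of the other state, and the bases in common made up 61.7% of all covered bases. H3K27me3 broad peaks, 130668 in QSC and 95819 in ASC, overlapped for 61.0% and 65.5%, and narrow peaks, 44019 and 58454, for 65.3% and 39.6%. The bases in common made up 52.5% for broad and 36.2% for narrow H3K27me3 peaks. H3K4me3 peaks lay at a protein-coding gene end for 76.3% in QSC and 74.8% in ASC, and H3K27me3 broad peaks for 7.32% and 10.1%.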

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

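The tests of weaker QSC enrichment, of ubiquitously expressed genes and of the broad H3K27me3 lists were chosen after their results had been seen, and so was the use of the planned settings of equal numbers of peaks and equal covered bases to weigh an explanation. Those of matched lists for the cell cycle genes, of H3K4me3 peak width and of H3K27me3 below the QSC threshold were set before their own results were seen. The QSC broad list for H3K4me3, used in the report for alternatives and to rule out peaks of the other state, holds 170362 peaks that touch no H3K4me3 narrow peak of either state. They make up 92.3% of that list and cover 196 Mb, with a median fold of 1.58, and 50 of them have a q value of at most 0.05. The ASC broad list holds 15193 such peaks (51.9%), of which 271 have a q value of at most 0.05.

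More genes had H3K4me3 in ASC only (775) than in QSC only (170), and a larger number of ASC peaks is not the whole cause, since with equal numbers of peaks the difference was still 247. Weaker H3K4me3 enrichment in the QSC material stays open: 89.7% of the ASC-only genes had a QSC broad-list peak in the window, against 34.5% of genes with no narrow peak in either state, so many of these may be marked in QSC below the threshold. With the states exchanged the shares were 91.2% and 13.6%, so calls near the threshold occur in both directions and the test does not single out QSC. With equal covered bases the difference was -3406, which decides little because the wide ASC peaks used up the bases and 49.6% of them were kept. A change of the mark on activation is the biological explanation that the groups allow, and it was not tested apart from these.

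Cell cycle genes had the largest list median for longer H3K4me3 domains in ASC. General lengthening of ASC domains would have placed this list within random lists matched on mean domain length, yet it lay above 100% of them, and it also lay above 100% of lists matched on fold rank, which argues against stronger lengthening at strongly enriched genes as the whole cause. The ubiquitously expressed reference list lay above 99.99% of its own fold-matched lists, so the lengthening was not confined to the cell cycle and may extend to other actively transcribed genes. Glycolysis and ribosome lists lay above 98.6% and 95.7% of theirs, but quiescence and immediate early lists above 0%. Lengthening was thus not common to all marked lists. Expression was not measured in the data used here, and a link to transcription stays open.

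Bivalent genes were 1.93 times as many in ASC as in QSC. With all H3K4me3 peaks set to 1 kb the ratio was 1.91, so the width of these peaks does not account for the count as called. The call needs both marks in the same window and no contact between them. The test therefore cannot exclude that the marks lie side by side. Permissive broad lists do not account for the ratio, because it was 3.09 with narrow lists. H3K27me3 below the QSC threshold stays open, because its test cannot decide it. Of the 802 genes with H3K4me3 alone in QSC and bivalent in ASC, 87.5% had a QSC broad peak within 5 kb of either end. For genes with H3K4me3 alone in both states the share was 55.0%. With the states exchanged, it was 86.7% for the 113 genes that went the other way. These are called peaks of the same list, and H3K4me3 alone means only that the marks shared no end. The shares thus measure nearness to called H3K27me3 and not signal below a threshold. Gain of H3K27me3 on activation remains a possible explanation that these lists cannot separate from a difference in sensitivity.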

How the results depend on the processing

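The narrow lists for both marks, the q of at most 0.05, the single gene end, the H3K4me3 peaks of 1 kb and the matched random lists were chosen after the data were seen; the other settings were fixed beforehand. Below, same means within a factor of 1.5 of the reported value, or for peak sharing within its 95% interval. Reversal was scored only for differences between the states and for the H3K4me3 domain length ratio, so a single count could not reverse. Among the main results 74 alternative values stayed the same in this sense, 60 moved and 3 reversed. Among gene list counts 132 stayed and 63 moved, and among counts of named genes 38 stayed and 14 moved. Where no cause is given, the cause was not tested. No paired analysis was possible because the lists hold no separate replicates. Transcript-start windows, GC-matched random lists and leaving out a replicate were not run. Unknown depth limits every count here, since a deeper library yields more and wider peaks.

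Equal covered bases reversed the H3K4me3 difference (ASC only minus QSC only) from 605 to -3406 and the bivalent difference (ASC minus QSC) from 1083 to -706. By construction, the wide ASC peaks use up the bases. H3K4me3 in QSC only went from 170 to 3508 and in ASC only from 775 to 102, and bivalent promoters in ASC from 2251 to 462. The H3K4me3 ASC-only counts became 3 for cell cycle, 0 for extracellular matrix, 0 for neural regulators and 1 for mesoderm and endoderm regulators. With equal numbers of peaks H3K4me3 in QSC only was 318, and the ASC-only counts were 2 for extracellular matrix, 3 for neural and 3 for mesoderm and endoderm regulators.

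The other list of each mark reversed the H3K4me3 difference to -1920, with 2460 genes in QSC only. The ASC-only counts were 0 for cell cycle, 1 for extracellular matrix and 1 for neural regulators. For H3K4me3 that setting uses broad lists of 184538 peaks over 254.9 Mb in QSC and 29297 over 88.8 Mb in ASC. Of these, 93.5% and 53.1% had a q value above 0.05. QSC calls rise with this much longer list, so the reversal decides little about the ASC excess. That setting and the narrow lists for both marks share their H3K27me3 calls: 194 genes in QSC only, and in ASC only 2 quiescence, 1 myogenic, 2 sarcomere, 10 Wnt, 6 extracellular matrix, 2 immune and 2 pericyte genes. With narrow lists for both marks, bivalent promoters were 366 in QSC and 1131 in ASC.

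With a -log10 q of at least 5, H3K27me3 was called at 3 genes in QSC only and 922 in ASC only, and bivalent promoters were 8 and 371. Only 71 broad H3K27me3 peaks in QSC and 874 in ASC passed this limit, so the small QSC counts follow from a nearly empty list. The H3K27me3 ASC-only counts were 2 for quiescence, 1 for myogenic, 1 for sarcomere, 10 for Wnt, 2 for extracellular matrix, 0 for immune and 2 for pericyte genes. With a fold of at least 3 the totals were 151 and 704, with 228 and 594 bivalent, and the list counts 0 for quiescence, 0 for myogenic, 2 for sarcomere, 1 for extracellular matrix, 0 for immune and 2 for pericyte genes. With a q of at most 0.05, H3K27me3 in QSC only was 207 and bivalent promoters 580 and 1438, with list counts of 2 for quiescence, 2 for myogenic, 3 for sarcomere and 9 for Wnt genes.

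A window of 2.5 kb gave 2520 bivalent promoters in QSC and 3875 in ASC, and H3K27me3 ASC-only counts of 8 for quiescence, 3 for Wnt and 2 for immune genes. The larger overlap gave 774 bivalent promoters in QSC. With all annotated genes the H3K4me3 counts were 261 in QSC only and 1219 in ASC only, and those of H3K27me3 2487 and 3923. With a single gene end H3K27me3 was called at 112 genes in QSC only and 775 in ASC only, and at 0 sarcomere, 2 Wnt and 0 immune genes in ASC only. These counts cover only genes with H3K4me3 at a single end, and only H3K27me3 at that end. Low values there can thus come from a lack of H3K4me3. With H3K4me3 peaks of 1 kb, 525 genes were called in QSC only.

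Peak sharing for H3K4me3, QSC then ASC, was 76.4% and 69.1% when the overlap had to reach 0.5 of both peaks, 92.1% and 91.6% with equal numbers of peaks, and 96.6% and 85.0% with a -log10 q of at least 5. For H3K27me3 it was 19.6% and 26.8%, 68.3% and 57.5%, and 83.1% and 6.87%, and with narrow lists 65.3% and 39.6%. The 83.1% and 6.87% rest on the 71 QSC and 874 ASC broad peaks that passed the q limit. H3K27me3 domains over 50 kb numbered 664 in QSC and 911 in ASC with a merging gap of 1 kb, and 3887 and 3869 with 10 kb.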

Other observations

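Gene families were grouped by the stem of their symbols after the data were seen. Zinc finger genes with the stem Zfp ran against the general increase of H3K27me3 broad-peak calls in ASC: 150 of 397 were called in QSC by broad peaks and fewer in ASC, with 23 called in ASC only and 69 in QSC only. By narrow peaks 19 were called in QSC and 27 in ASC, the direction of all genes (2054 and 3337). The clustered protocadherins of the stem Pcdhb went from 21 to 18 of 22 by broad peaks, with none by narrow peaks in either state.

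Many families had more H3K27me3 calls in ASC, and others, such as Serpinb (12 and 9 of 28 by broad peaks), had fewer; those named here were chosen after their values were seen. Whey acidic protein domain genes (Wfdc) had narrow peaks at 6 of 18 genes in QSC and 18 in ASC, and keratin genes (Krt) at 20 and 33 of 53. Members of these families lie in clusters and can share peaks, and the families were chosen for their values, so no place among random lists is given. Broad peaks were already present at all 18 Wfdc genes in both states and at 52 Krt genes in both. The Rhox homeobox genes, a cluster on the X chromosome expressed in reproductive tissue, had broad peaks at 0 of 33 genes in QSC and 18 in ASC, with narrow peaks at 0 and 2. Kallikrein genes (Klk) went from 15 to 23 of 26 by broad peaks.

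The X chromosome carried little H3K27me3 by these lists. Of its 966 protein-coding genes, 6.83% were called in QSC and 12.2% in ASC, against 31.9% and 35.7% of autosomal genes. For H3K4me3 the shares were 34.7% and 38.6% on X and 54.5% and 57.2% on the autosomes.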
